A study of Mus musculus with 17 samples.

How the data were processed

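RNA was measured by sequencing in hepatocytes sorted by FACS from livers of male mice aged 2 to 3 months. The 17 samples fall into 4 groups by genotype (wild type or Yap/Taz knockout) and treatment (untreated or carbon tetrachloride, CCl4). Per the labels, CCl4 was given at 1 ug/g in 7 doses, 1 every 3 days, and hepatocytes were gathered 3 days after the last dose. RNA was purified with a Qiagen MicroRNEasy kit and libraries were made with the NEBNext Ultra II RNA kit, per the labels.

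The authors deposited 1 table of counts per gene, with 1 column per sample, and its values were whole numbers with totals that differed between samples. Per the submitters' processing notes, reads were aligned with STAR 2.4.1d to mm10, FastQC was run, and DESeq2, edgeR and limma were also named. The tool that counted reads per gene, its strand setting and the annotation release are not given in the sources used here. The table held 23461 genes, of which none was at 0 in every sample. Gene symbols were matched for 22914 identifiers and mm10 positions, from GENCODE, for 22929. Totals per sample ran from 11266420 to 24775863 counts, with a median of 14786573. Pairs of replicate columns were checked for splits of 1 library: over genes with at least 20 counts in the pair, the lowest chi-square per gene was 23.4.

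Counts were analysed in R 4.3.3 with edgeR 4.0.16, all 17 samples in 1 fit with a mean per group. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 13721. Libraries were scaled by TMM, dispersions were estimated with robust estimation, and each contrast was tested by the quasi-likelihood F test with robust estimation. P values were adjusted by Benjamini-Hochberg (BH) over the genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p values given for genes are from edgeR unless another tool is named. Errors of log2 fold changes are standard errors, taken as the size of the log2 fold change over the square root of F. Gene levels are CPM of the TMM-scaled library sizes, given as mean ± SD. Summed cell-type markers are CPM of the unscaled total counts.

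The contrasts were CCl4 against untreated within each genotype, knockout against wild type within each treatment, and the difference of the CCl4 effect between genotypes. Replicate numbers pair no samples, per the labels, so no pairing was used. The levels of Yap1, Wwtr1 and Ccn1 were also compared by two-sided exact permutation tests on log2 CPM with 0.1 CPM added, BH-adjusted over 12 tests. Ccn1 was added after its values were seen, so its p values from these tests are not given. Summed Mup levels were compared the same way, BH-adjusted over 4 tests.

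Before the counts were seen, 32 gene lists with 705 entries were fixed, covering hepatocyte functions, stress responses, YAP/TAZ-TEAD targets and markers of other liver cells; 696 entries were in the table. Lists with at least 5 tested members were tested against all other genes by camera (limma 3.58.1) with a preset correlation of 0.01. P values were BH-adjusted over the lists. The same lists were tested by camera with an estimated correlation and by fry. Lymphocyte, neutrophil, and erythroid and platelet markers had too few tested members and are given as summed CPM.

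Named genes followed a rule fixed before the counts were seen. They are Yap1 and Wwtr1 in every comparison, and the 10 largest rises and 10 largest falls per comparison between groups, among called genes with a mean CPM of at least 10 in the higher group. For the difference of CCl4 effects the 10 called genes with the smallest p were taken. From each list, up to 4 members with the smallest adjusted p were named. Genes named outside this rule are marked as chosen after their values were seen.

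A gene with 0 counts in a group is given a fold of at least the ratio to a floor of 3 counts over that group. With 1 to 3 counts, the ratio of counts is given with its 95% counting interval. These bounds and intervals cover counting error only.

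Alternatives set before the counts were seen were RLE, upper-quartile and unscaled library totals, no filter, a filter of CPM at least 1 in at least 5 samples, DESeq2 1.42.0, limma voom with and without sample quality weights, fits of the 2 compared groups only, the replicate number as a block, 1 surrogate variable (sva 3.50.0), the estimated correlation, genes with a mean CPM of at least 1, and leaving out each sample. Leaving out the 2 libraries with over 30% mitochondrial counts, and leaving out mitochondrially encoded genes, were added after the data were seen. The pipeline was tested on simulated data: counts of 100 genes were changed 2-fold and of 100 others 4-fold. In the contrasts of 2 groups it recovered 18 to 44% of the 2-fold and 71 to 81% of the 4-fold changes, and in the difference of CCl4 effects 6% and 58%. No sample and no column was left out.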

Results

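Messenger RNA was counted in FACS-sorted hepatocytes of male mice, wild type or with Yap and Taz (gene Wwtr1) knocked out, left untreated or given repeated CCl4, a solvent toxic to the liver. There were 5 wild type untreated, 5 wild type CCl4, 4 knockout untreated and 3 knockout CCl4 samples. The samples are separate by the labels, which do not say that each came from its own animal. Totals per sample ran from 11266420 to 24775863 counts over 23461 genes. The first component of the 13721 tested genes held 36.0% of the variance. Knockout CCl4 replicate 3 had a mean correlation of 0.866 with its group, against 0.904 and 0.903 for replicates 1 and 2 of that group. Mitochondrially encoded genes held 34.3% of counts in knockout CCl4 replicate 3 and 30.7% in wild type untreated replicate 5.

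The targeted genes were lower in every knockout sample than in any wild type sample. Yap1 (ENSMUSG00000053110, mm10 chromosome 9, 7931999 to 8004596), a transcriptional coactivator restrained by the Hippo kinases, had 51.2 ± 13.4 CPM (SD, n = 5) in wild type untreated and 3.50 ± 3.08 (n = 4) in knockout untreated samples. After CCl4 it had 55.1 ± 8.41 (n = 5) in wild type and 1.37 ± 0.746 (n = 3) in knockout. Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910), which encodes its relative TAZ, had 12.8 ± 3.53 and 1.87 ± 0.664 CPM untreated, and 19.6 ± 3.23 and 4.76 ± 2.20 after CCl4, in wild type and knockout. Exact two-sided permutation p values for both genes were 0.00794 untreated and 0.0179 after CCl4, the smallest these group sizes allow, with a BH-adjusted p of 0.0408. Wwtr1 was higher after CCl4 than without it within the knockout, by 1.33 ± 0.33 log2 (adjusted p = 0.00918). Without knockout CCl4 replicate 3 that value was 0.94 (adjusted p = 0.0754). In wild type its mean was also higher after CCl4, by 0.62 ± 0.26 log2 (adjusted p = 0.269). Exact permutation p values for these 2 CCl4 comparisons were 0.0286 in knockout (BH-adjusted 0.0429) and 0.0238 in wild type (BH-adjusted 0.0408).

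Ccn1, a direct target of the YAP/TAZ-TEAD complex and chosen after its values were seen, had 22.9 ± 18.2 CPM in wild type untreated and 60.9 ± 20.3 in wild type CCl4 samples (n = 5 each). It had 21.5 ± 14.7 (n = 4) in knockout untreated and 15.5 ± 11.1 (n = 3) in knockout CCl4 samples. For knockout against wild type after CCl4, the model across all genes gave a log2 fold change of -1.99 ± 0.70 with an adjusted p of 0.0756, short of the threshold. Of the 16 tested YAP/TAZ-TEAD targets, none passed in the untreated knockout (adjusted over the list alone, 1 rose), and the list's camera adjusted p was 0.648. After CCl4, Axl and Myof were higher in knockout than in wild type, by 5.27 ± 0.92 and 4.82 ± 0.95 log2, and 14 members did not pass. Adjusted over the list alone 2 rose. Without knockout CCl4 replicate 3 these values were 3.13 (adjusted p = 0.0686) and 2.93 (adjusted p = 0.103).

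**Figure D1:**
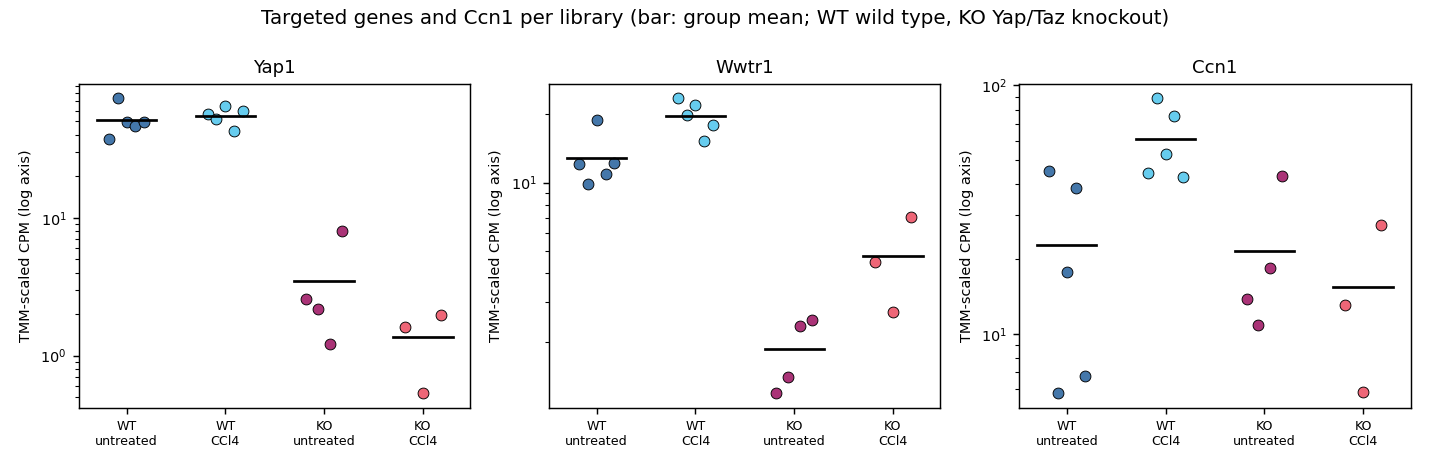
CPM of Yap1, Wwtr1 and Ccn1 per library on log axes, by group (5, 5, 4 and 3 libraries), with a bar at each group mean. Every knockout library lies below every wild type library for Yap1 and Wwtr1, with means of 3.50 against 51.2 CPM for Yap1 without CCl4.

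Repeated CCl4 in wild type hepatocytes asks what chronic injury changes when Yap and Taz are present. The major urinary protein genes, pheromone carriers made by the male liver, fell: Mup7 (ENSMUSG00000073842, chromosome 4, 60066469 to 60070475) went from 18085 ± 9883 to 406 ± 156 CPM (n = 5 each; log2 -5.48 ± 0.88, adjusted p = 0.00664). Mup15 had 0 counts after CCl4 and was at least 38400-fold lower. Lpl (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), the lipase of circulating triglyceride, rose by 2.79 ± 0.40 log2. Golm1 (ENSMUSG00000021556, chromosome 13, 59634626 to 59675811), a Golgi protein known from diseased liver, rose by 2.67 ± 0.27 (adjusted p = 0.000149). Cd63, a late endosome tetraspanin, rose by 3.28 ± 0.55, and Nid1, a basement membrane protein, by 2.82 ± 0.49. In each of these, all 5 CCl4 libraries lay beyond all 5 untreated libraries, as for 38 of the 41 named genes called in this comparison. Named genes were picked among called genes for large changes or small p, so separation was close to fixed in advance and adds no support.

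The other largest rises, Fosb, Cyp4a14, Cyp4a31, Hes1, Klf6 and H2-Q1, had log2 fold changes of 5.06, 3.11, 2.34, 2.28, 2.21 and 2.18. Of these 6 genes only Klf6 passed whichever library was left out, and Cyp4a14 reached an adjusted p of 0.112 without wild type untreated replicate 2 (log2 2.91). The falls were 9 Mup genes or pseudogenes and the neighbouring model Gm13775, on chromosome 4. Mup sequences are close copies, so single members are uncertain. Summed over 41 Mup genes, a sum added after the data were seen, levels were 84231 ± 31633 CPM without and 16976 ± 2462 with CCl4 (n = 5 each; exact permutation p = 0.00794, BH-adjusted 0.0317).

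Genes with sex-biased expression moved together in wild type. Of 22 male-biased liver genes 5 fell and none rose (15 fell adjusted over the list alone; camera adjusted p = 4.88e-23, and adjusted p = 0.0321 with an estimated correlation). Hsd3b5, a hydroxysteroid dehydrogenase, fell by 3.46 ± 0.47 log2, and Susd4, a complement regulator, by 2.53 ± 0.32. Of 17 female-biased genes 2 rose, Cyp2a4 by 3.24 ± 0.63 and Cyp3a44 by 3.01 ± 0.63 (7 rose adjusted over the list alone; adjusted p = 3.83e-08, and adjusted p = 0.0137 with an estimated correlation). Cyp2a4 reached an adjusted p of 0.0709 without wild type untreated replicate 3 (log2 3.09), and Cyp3a44 reached 0.0946 without wild type CCl4 replicate 5 (log2 2.81). Of 7 fetal liver genes 2 rose (3 adjusted over the list alone; adjusted p = 0.000213, and adjusted p = 0.0321 with an estimated correlation). They were H19, an imprinted noncoding RNA, at least 54.8-fold, and Dlk1, a Notch-like ligand, with a count ratio of 60.8 (95% interval 10.7 to 2420). Dlk1 reached an adjusted p of 0.0814 without wild type untreated replicate 2, with log2 5.32 against 5.52, from few counts. With 1 library left out at a time 5 to 9 male-biased genes fell (9 without knockout CCl4 replicate 1), and 0 to 4 female-biased (0 without wild type untreated replicate 2) and 1 to 2 fetal genes rose.

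Of 24 genes of fatty acid oxidation and PPARA targets 2 rose, the thioesterase Acot2 by 2.21 ± 0.32 and Cyp4a14 (5 adjusted over the list alone; adjusted p = 1.26e-05, and adjusted p = 0.204 with an estimated correlation). Apoa4, an apolipoprotein on the periportal list, rose by 1.88 ± 0.25, and Slc1a4, an amino acid transporter on the pericentral list, by 2.15 ± 0.34. Gstp1, a glutathione transferase, fell by 1.42 ± 0.19. Of 30 cell-cycle genes 1 rose, the replication helicase subunit Mcm6 by 1.61 ± 0.33 (2 rose and 1 fell adjusted over the list alone; adjusted p = 1.31e-05, and adjusted p = 0.316 with an estimated correlation). Mcm6 reached an adjusted p of 0.0803 without wild type untreated replicate 3 (log2 1.47). The median of the cell-cycle list was 0.40 log2, and 1.60 with 5 genes rising without wild type untreated replicate 5. That library had 441 CPM of summed cell-cycle genes, against 100 to 141 in the other 4 untreated and 161 to 284 in the 5 CCl4 libraries. Of 23 immediate-early and dissociation response genes 2 rose, Fosb and Klf6 (3 adjusted over the list alone; adjusted p = 1.95e-07, and adjusted p = 0.186 with an estimated correlation).

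A minority of the markers of other liver cells passed over all genes in the same libraries, though their lists rose. The medians were 2.58 log2 for endothelial, 2.03 for stellate and 1.93 for macrophage markers. For the genes named in this comparison, RNA of other cells was not told apart from a change within hepatocytes. Of 20 endothelial markers 2 rose, Lyve1 by 4.30 ± 0.85 and Ramp2 by 4.20 ± 0.89 (19 adjusted over the list alone; adjusted p = 6.22e-17, and adjusted p = 0.14 with an estimated correlation). Of 18 stellate and myofibroblast markers 1 rose, Col3a1, a fibrillar collagen, by 3.79 ± 0.79 (9 adjusted over the list alone; adjusted p = 1.4e-08, and adjusted p = 0.204 with an estimated correlation). None of 23 macrophage markers passed (1 rose adjusted over the list alone; adjusted p = 1.46e-06, and adjusted p = 0.316 with an estimated correlation). Lyve1 reached an adjusted p of 0.07, Col3a1 of 0.0869 (each without wild type untreated replicate 2) and Ramp2 of 0.0806 (without replicate 1), with log2 fold changes of 4.12, 3.65 and 3.96. With 1 library left out at a time 0 to 5 endothelial markers rose (5 without knockout CCl4 replicate 3). Endothelial markers summed to 35.3 ± 21.9 CPM untreated and 156 ± 103 after CCl4, stellate markers to 17.6 ± 6.07 and 78.9 ± 50.3, and macrophage markers to 46.7 ± 20.3 and 107 ± 40.9 (n = 5 each). Mpeg1 alone averaged 42.3 CPM untreated and 41.0 after CCl4 on the TMM scale, so the macrophage sum understates the rise of the other markers. Mitochondrially encoded genes held 5.32 to 30.7% of counts untreated and 1.98 to 10% after CCl4.

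By edgeR with BH adjustment 117 genes were called after CCl4 in wild type, 79 higher and 38 lower, with 2023 at an unadjusted p under 0.05. The count was 67, 63, 74 and 69 without wild type untreated replicates 2 and 3 and wild type CCl4 replicates 2 and 5 in turn, and 179 without knockout CCl4 replicate 3. With library totals alone, which moved the median of all genes by 0.39 log2, 650 genes were called and 94.8% were higher, against 67.5% with TMM.

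**Figure D2:**
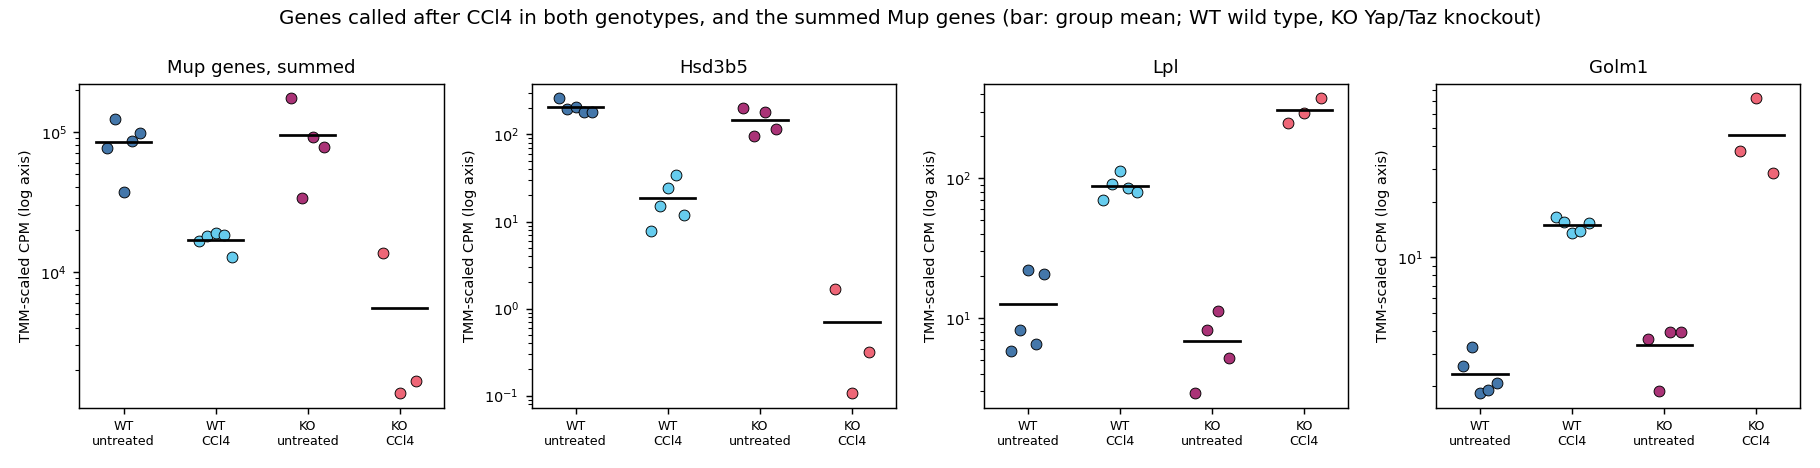
CPM per library on log axes of the summed Mup genes, Hsd3b5, Lpl and Golm1, by group (5, 5, 4 and 3 libraries), with a bar at each group mean. Hsd3b5 averaged 205 CPM in wild type untreated, 18.7 in wild type CCl4, 149 in knockout untreated and 0.698 in knockout CCl4 libraries.

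Repeated CCl4 in knockout hepatocytes asks the same question without Yap and Taz. Cyp2a4 (ENSMUSG00000074254, chromosome 7, 26307169 to 26315088), a female-biased steroid hydroxylase, rose by 9.88 ± 0.95 log2, and Gsta1 (ENSMUSG00000074183, chromosome 9, 78230656 to 78242684), a glutathione transferase, by 6.52 ± 0.56. Ly6d, a surface protein of epithelial and B lineage cells, rose with a count ratio of 4170 (95% interval 749 to 165000), and Cyp2b9, female-biased, rose at least 729-fold. Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252) fell by 7.79 ± 0.77 and Slc22a28, a solute carrier of the organic anion family, fell by 5.36 ± 0.80. The sulfotransferase Sult1e1, which inactivates oestrogens, rose by 7.29 ± 1.06. Slc22a28 stood at 1.19, 0 and 0.0787 CPM in the 3 knockout CCl4 libraries, so its size is uncertain (-9.02 without replicate 1). Of 106 named genes called here, 102 separated all 3 CCl4 from all 4 untreated libraries, which follows largely from how they were picked. Groups of these sizes separate by chance in 5.71% of cases.

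Cell-cycle genes rose in the injured knockout: 26 of 30 rose, 27 adjusted over the list alone, and 25 without knockout CCl4 replicate 3. The helicase subunits Mcm6 and Mcm2 rose by 3.14 ± 0.40 and 3.13 ± 0.41 log2, the ribonucleotide reductase subunit Rrm2 by 2.81 ± 0.38, and E2f1, which drives entry into S phase, by 1.83 ± 0.24. The camera adjusted p was 6.76e-22, and adjusted p = 0.0546 with an estimated correlation. Of 21 p53 targets 7 rose, among them Phlda3, an inhibitor of Akt, by 4.57 ± 0.64 and Eda2r by 2.51 ± 0.58 (9 adjusted over the list alone; adjusted p = 5.78e-05, and adjusted p = 0.0546 with an estimated correlation).

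Hepatocyte lists moved in both directions. Of 22 male-biased genes 19 fell (20 adjusted over the list alone; adjusted p = 7.12e-23, and adjusted p = 0.0189 with an estimated correlation), and 7 of 17 female-biased genes rose (7 adjusted over the list alone; adjusted p = 6.26e-07, and adjusted p = 0.0189 with an estimated correlation). Of 21 periportal genes 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 3.34e-06, and adjusted p = 0.139 with an estimated correlation). Cyp2f2 fell by 2.45 ± 0.45 and Pigr, the transporter of immunoglobulin A, by 1.40 ± 0.20, while Apoa4 rose by 3.16 ± 0.31. Of 19 genes of bile acid synthesis and transport 9 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 1.59e-05, and adjusted p = 0.0837 with an estimated correlation). The uptake carrier Slco1a1 fell by 3.37 ± 0.50, the hydroxylase Cyp7b1 by 3.89 ± 0.62 and the bile acid ligase Slc27a5 by 1.05 ± 0.20. Of 27 hepatocyte identity genes 11 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 6.47e-05, and adjusted p = 0.139 with an estimated correlation). Tdo2, which opens tryptophan breakdown, fell by 1.55 ± 0.29 and the antitrypsin gene Serpina1c by 1.34 ± 0.27. Of 30 genes of the NRF2 antioxidant response 12 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.000152, and adjusted p = 0.157 with an estimated correlation), with Gstm3 up by 4.08 ± 0.55 and Srxn1 by 2.34 ± 0.38 (1.47 without Yap/Taz knockout CCl4 replicate 2). Of 7 fetal genes 4 rose (4 adjusted over the list alone; adjusted p = 0.00113, and adjusted p = 0.0546 with an estimated correlation), with Afp up by 3.74 ± 0.67. With knockout CCl4 replicate 3 left out, 7 hepatocyte identity genes fell.

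Of 23 pericentral genes 6 rose and 1 fell after CCl4 in knockout (7 and 3 adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.569 with an estimated correlation), with Slc1a4 up by 4.93 ± 0.42. With knockout CCl4 replicate 3 left out, 3 rose. The camera call was lost when knockout untreated replicate 1 or 2 or knockout CCl4 replicate 2 was left out, with an adjusted p up to 0.568.

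Macrophage, endothelial and stellate markers rose in the same 3 libraries. All 23 macrophage markers rose (23 adjusted over the list alone; adjusted p = 2.97e-15, and adjusted p = 0.139 with an estimated correlation), with Gpnmb at 0.0912 CPM in untreated and 203 ± 295 in CCl4 knockout samples (32.9 without knockout CCl4 replicate 3). Of 20 endothelial markers 19 rose (19 adjusted over the list alone; adjusted p = 4.44e-11, and adjusted p = 0.167 with an estimated correlation). Of 18 stellate markers 15 rose (16 adjusted over the list alone; adjusted p = 1.07e-09, and adjusted p = 0.157 with an estimated correlation). Of 13 profibrotic ligands and matrix regulators 11 rose (11 adjusted over the list alone; adjusted p = 5.52e-07, and adjusted p = 0.0837 with an estimated correlation), with the membrane protease Mmp14 up by 1.83 ± 0.30 and the ligand Tgfb1 by 4.90 ± 0.92. Of 17 inflammatory genes 12 rose (13 adjusted over the list alone; adjusted p = 3.34e-06, and adjusted p = 0.185 with an estimated correlation), with Icam1 up by 2.17 ± 0.39. Without knockout CCl4 replicate 3 the numbers rising were 19, 7, 9, 7 and 5 for these 5 lists, and Tgfb1 and Icam1 rose by 2.64 and 1.44.

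By edgeR 2610 genes were called after CCl4 in knockout, 1655 higher and 955 lower, and 1666 without knockout CCl4 replicate 3. With library totals alone the median of all genes moved to 0.20 log2 and 83.5% of 2162 calls were higher, against 63.4% with TMM. The log2 changes after CCl4 in the 2 genotypes, from separate samples, correlated across 13721 genes with r = 0.531 and rho = 0.403 (genes are not independent replicates). Of the called genes 67 were higher in both (9.53 by independence) and 32 lower in both (2.64), and 0 were opposite.

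**Figure D3:**
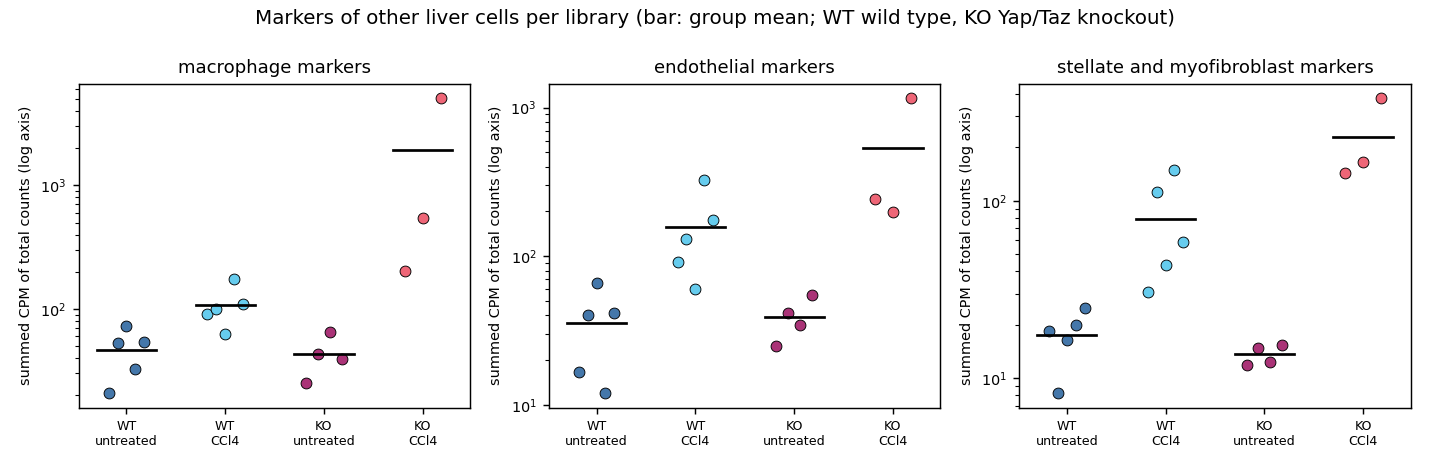
Summed CPM of total counts of macrophage, endothelial, and stellate and myofibroblast markers per library on log axes, by group (5, 5, 4 and 3 libraries), with a bar at each group mean. Macrophage markers summed to 201, 548 and 5057 CPM in the 3 knockout CCl4 libraries, against a mean of 107 in wild type CCl4 libraries. On average Mpeg1 made up most of the macrophage sum in untreated libraries.

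Knockout against wild type without injury asks what Yap and Taz do in resting adult hepatocytes. Several of the largest changes lay in genes with close copies. Rps3a1 (ENSMUSG00000028081, chromosome 3, 86137940 to 86142702), a ribosomal protein gene, fell from 225 to 3.30 CPM (log2 -6.09 ± 0.37, adjusted p = 1.34e-07). Its copies Rps3a2 (chromosome 14, 88123017 to 88123808) and Rps3a3 (chromosome 13, 108670603 to 108671397) rose from 0.367 to 136 and from 0.162 to 83.1 CPM. Their sum was 225 ± 13.1 CPM in wild type (n = 5) and 222 ± 18.5 in knockout (n = 4). Counts of these genes are therefore uncertain one by one. Rpl34, another ribosomal protein gene, fell from 57.7 to 1.72 CPM.

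**Figure D4:**
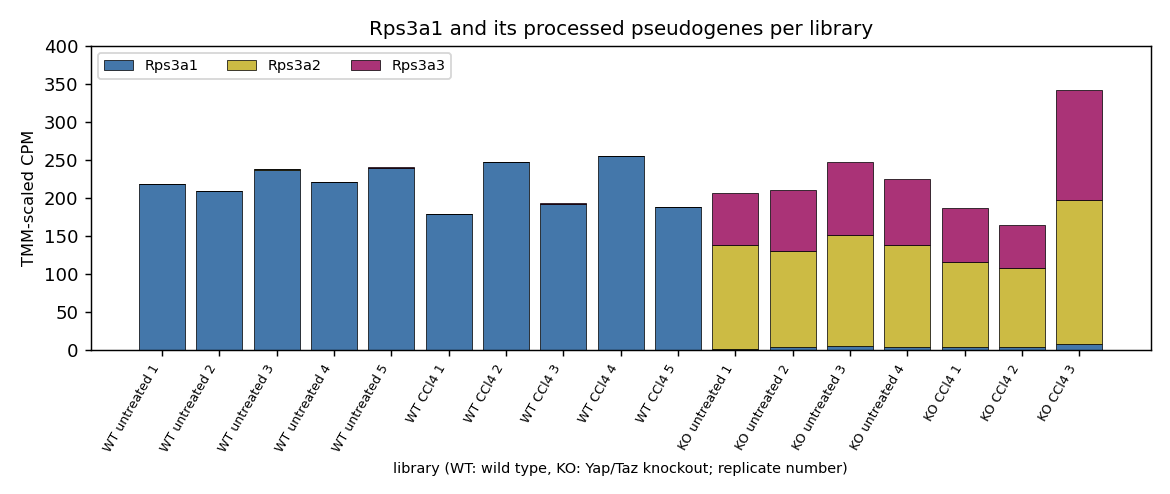
CPM of Rps3a1, Rps3a2 and Rps3a3 stacked per library, all 17 libraries in group order. Rps3a1 fills almost the whole bar in wild type libraries, and Rps3a2 and Rps3a3 do so in knockout libraries.

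Among other genes, Ugt2b38 (ENSMUSG00000061906, chromosome 5, 87409942 to 87424203), a male-biased glucuronosyltransferase of a multigene family, fell from 32.5 to 0.193 CPM. Tdg (ENSMUSG00000034674, chromosome 10, 82629828 to 82650799), a DNA repair glycosylase, fell from 13.7 to 1.04 CPM. Parent and copies were summed for the Rps3a genes only. Reads moving to copies were therefore not checked for Tdg, Ugt2b38 or Rpl34. Mme (chromosome 3, 63241537 to 63386030), a membrane peptidase, fell by 3.76 ± 0.54 log2. Mme was the next called gene after the targeted Wwtr1 on that chromosome. Sequence carried with the targeted allele cannot be told apart there from an effect of Yap and Taz loss. Fam171b (ENSMUSG00000048388, chromosome 2, 83812636 to 83883486) rose from 0.0712 to 33.0 CPM. Models and pseudogenes among the largest rises were Gm9825 (at least 315-fold), Gm26825 (1.01 to 398 CPM), Gm6311, Gm10020, Gm9855 and 2 genes without a symbol, and among the falls Mup19, Gm4956 and Adh6-ps1. All 26 named genes called here separated the 4 knockout from the 5 wild type libraries, which again follows largely from how they were picked.

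Few members of the fixed lists passed in untreated hepatocytes. Apoa4 and the dehydratase Sdsl rose by 1.3 ± 0.26 and 1.17 ± 0.26 log2, the steroid hydroxylase Cyp17a1 rose by 1.90 ± 0.42, and Gsta3 and Gsta1 fell by 1.28 ± 0.22 and 2.56 ± 0.50. Only Gsta3 of these passed whichever library was left out, and Sdsl reached an adjusted p of 0.173 without knockout untreated replicate 1 (log2 0.77). By camera 12 lists passed, the lowest being cell cycle, lower in knockout (adjusted p = 7.68e-09), and none passed with an estimated correlation (adjusted p = 0.632 for cell cycle, lowest adjusted p = 0.46 for cytochrome P450 genes). None of 30 cell-cycle genes passed over all genes, and 18 fell adjusted over the list alone. Without wild type untreated replicate 5, the library with 441 CPM of summed cell-cycle genes, the list's median was -0.9998 log2 against -2.06 (camera adjusted p = 7.76e-07).

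By edgeR 128 genes were called, 80 higher and 48 lower, with 1203 at an unadjusted p under 0.05. With library totals alone the median of all genes was 0.14 log2 and 74.2% of 124 calls were higher, against 62.5%. Without knockout untreated replicate 2, 7 lists passed.

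Knockout against wild type after CCl4 asks how injured hepatocytes differ without Yap and Taz. Macrophage and inflammatory genes were higher in knockout: Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, by 7.99 ± 0.97 log2, the cytokine gene Il1b by 7.66 ± 1.16 and the neutrophil attractant Cxcl2 by 7.47 ± 1.11. All 23 macrophage markers (23 adjusted over the list alone; adjusted p = 5.16e-12, and adjusted p = 0.294 with an estimated correlation) and 11 of 17 inflammatory genes (13 adjusted over the list alone; adjusted p = 2.74e-06, and adjusted p = 0.294 with an estimated correlation) were higher. Without knockout CCl4 replicate 3 these numbers were 4 and 3, and Gpnmb, Il1b and Cxcl2 were higher by 5.35, 3.30 and 3.33. The immunoglobulin gene Igha was higher by 7.43 ± 1.58, and by 2.65 (adjusted p = 0.417) without that library. Of 20 endothelial markers 5 were higher (11 adjusted over the list alone; adjusted p = 0.000137, and adjusted p = 0.465 with an estimated correlation), and 0 without that library.

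Apoa4 was higher in knockout by 2.53 ± 0.28 log2 (2.20 without knockout CCl4 replicate 3), and Afp, the fetal serum protein, by 2.87 ± 0.59 (2.97). Of 30 cell-cycle genes 8 were higher (18 higher and 1 lower adjusted over the list alone; adjusted p = 1.16e-07, and adjusted p = 0.294 with an estimated correlation), with Mcm5 at 2.27 ± 0.45. Without replicate 3 of the injured knockout 3 were higher, without its replicate 2 there were 2, and without wild type untreated replicate 5 there were 20. The list's median was 1.77 log2 with all libraries and 1.07 to 2.07 with 1 left out. Summed cell-cycle genes stood at 396, 1190 and 450 CPM in the 3 knockout libraries and at 161 to 284 in the 5 wild type libraries, and summed macrophage markers on the same scale at 176, 422 and 5883.

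**Figure D5:**
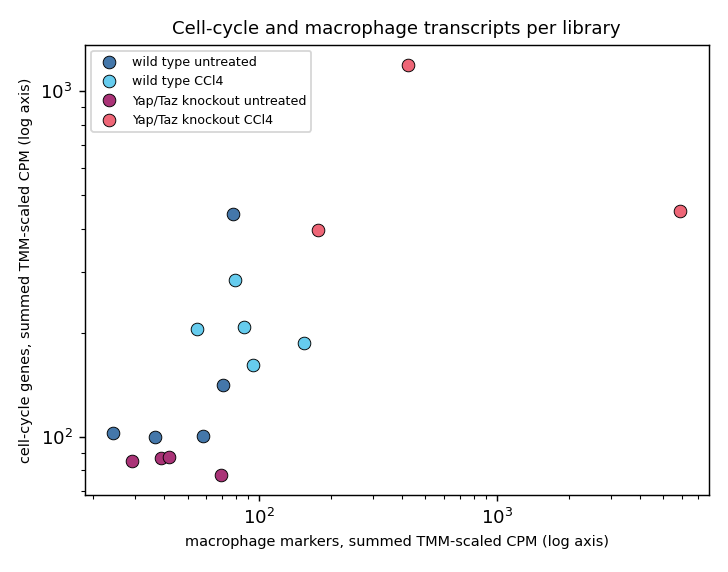
Summed CPM of 30 cell-cycle genes (vertical log axis) against summed CPM of macrophage markers (horizontal log axis), 1 point per library. Knockout CCl4 replicate 2 has 1190 CPM of cell-cycle genes with 422 of macrophage markers, and replicate 3 has 450 with 5883. On average Mpeg1 made up most of the macrophage sum in untreated libraries.

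A minority of the members of 5 hepatocyte lists were lower in the injured knockout. Of 19 bile acid genes 8 were lower, Slc27a5 by -1.30 ± 0.19 log2 (11 adjusted over the list alone; adjusted p = 2.42e-08, and adjusted p = 0.129 with an estimated correlation). Of 22 male-biased genes 8 were lower, with Hsd3b5 at -4.80 ± 0.68 and the selenium-binding Selenbp2 at -4.63 ± 0.75 (14 adjusted over the list alone; adjusted p = 2.68e-11, and adjusted p = 0.195 with an estimated correlation). Of 21 periportal genes 6 were lower and 1 higher (10 and 3 adjusted over the list alone; adjusted p = 0.000242, and adjusted p = 0.294 with an estimated correlation), with Pigr at -1.55 ± 0.20 and Hal, which opens histidine breakdown, at -1.64 ± 0.29. Of 32 cytochrome P450 genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 4.12e-05, and adjusted p = 0.294 with an estimated correlation), with Cyp2j5 at -1.23 ± 0.21. Of 24 fatty acid oxidation genes 5 were lower (7 adjusted over the list alone; adjusted p = 4.12e-05, and adjusted p = 0.294 with an estimated correlation). Without knockout CCl4 replicate 3 the numbers lower were 2 for bile acid, 4 for male-biased, 3 for periportal, 4 for cytochrome P450 and 2 for fatty acid oxidation genes. The medians of these 5 lists were -0.99, -1.25, -0.47, -0.59 and -0.36 log2 there, against -0.87, -1.54, -0.59, -0.63 and -0.62 with all libraries, and the lists still passed by camera with the preset correlation (highest adjusted p = 0.00636). Leaving out knockout CCl4 replicate 1 gave 10, 13 and 11 lower for bile acid, male-biased and periportal and 8 for fatty acid oxidation genes, with a male-biased median of -2.71, and leaving out replicate 2 gave 3 for cytochrome P450 genes. Hamp2 was lower by -4.10 ± 0.92, and by -3.89 without knockout CCl4 replicate 3 (adjusted p = 0.0772). Tdg, Ugt2b38, Rps3a1 and Rpl34 were lower and Rps3a2 (at least 4440-fold) and Rps3a3 higher, as without injury.

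By edgeR 1622 genes were called, 1045 higher and 577 lower. The count was 418 without knockout CCl4 replicate 3 and 1026 without wild type CCl4 replicate 2. Of 96 named genes called here, 83 separated the knockout from the wild type libraries. The knockout effects with and without injury, from separate samples, correlated across genes with r = 0.174 and rho = 0.0593, with 61 genes higher in both (6.09 by independence), 26 lower in both (2.02) and 2 opposite. Genes with close copies, such as Rps3a1 and Rps3a2, are among those shared. The overlap thus does not tell allele differences between the genotypes from an effect of Yap and Taz loss.

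Whether the CCl4 effect itself differs between genotypes was tested as the difference of the differences. Adh6-ps1, a pseudogene of alcohol dehydrogenase, had a difference of -4.08 ± 0.59 log2 and Gsta1 of 4.48 ± 0.65 (adjusted p = 0.0204 for each). For knockout against wild type, Gsta1 stood at -2.56 log2 untreated, from 34 counts over that knockout group, and at 1.92 after CCl4. Adh6-ps1 stood at -2.36 untreated and had 11 counts over the knockout CCl4 group. Gsta1 lies on chromosome 9 with Yap1, and Adh6-ps1 on chromosome 3 with Wwtr1. Cyp2c23, an epoxygenase (ENSMUSG00000025197, chromosome 19, 44005022 to 44029208), had -1.74 ± 0.27, with 406 and 326 CPM in wild type and 318 and 76.5 in knockout without and with CCl4. The mitochondrial carrier Ucp2 had 5.04 ± 0.80 and the potassium channel Kcnn2 -1.49 ± 0.24. By edgeR with BH adjustment 150 genes were called, 109 higher and 41 lower, with 2343 at an unadjusted p under 0.05. This count was 0 without wild type untreated replicate 4, wild type CCl4 replicate 4 or 5, or knockout untreated replicate 1 or 4. It was 16, 29, 2, 4, 6, 3 and 11 without wild type untreated 5, wild type CCl4 1, 2 and 3, knockout untreated 2 and 3 and knockout CCl4 3, and 867 without knockout CCl4 replicate 1. DESeq2 called 779 and limma voom 9. With library totals alone 28 were called, 60.7% higher against 72.7%, and the median of all genes moved to -0.16 log2.

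For lists, 19 passed in the difference by the preset correlation and none with an estimated correlation. Cell-cycle genes had 8 of 30 members with a larger rise in knockout (27 adjusted over the list alone; adjusted p = 9.51e-20, and adjusted p = 0.198 with an estimated correlation). Macrophage markers had 5 of 23 (18 adjusted over the list alone; adjusted p = 7.12e-16, and adjusted p = 0.198 with an estimated correlation), and male-biased genes had 1 of 22 with a larger fall, Hsd3b5 at -4.33 ± 0.79 (8 adjusted over the list alone; adjusted p = 1.68e-10, and adjusted p = 0.198 with an estimated correlation). With knockout CCl4 replicate 3 left out, edgeR called none of the members of these 3 lists, and 11 genes in all with 1625 at an unadjusted p under 0.05. The median differences were then 4.41 for cell cycle, 3.11 for macrophage markers and -1.17 for male-biased genes, against 4.20, 6.49 and -1.66 with all libraries, and the preset-correlation calls held (adjusted p = 8.52e-25, 9.93e-14 and 4.34e-08). The cell-cycle median was 2.71 without wild type untreated replicate 5 (adjusted p = 2.06e-23), and the male-biased median was -2.83 without knockout CCl4 replicate 1. Without that last library 22, 16 and 12 members of the 3 lists passed.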

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

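The tests of RNA from other cells, of a single library, of reads moving between a parent gene and its copies, and of called genes lying close together were chosen only after the result was seen. The contrasts, gene lists, thresholds and naming rule were set before the data were examined.

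Macrophage transcripts were higher in the injured knockout than in the injured wild type, in cells sorted by FACS as hepatocytes. RNA of other cells in the sorted fraction cannot be told apart from a biological rise: 100% of the 23 tested macrophage markers were higher, which restates the pattern, with Lyz2 at 377 ± 575 and Csf1r at 157 ± 229 CPM in the injured knockout (n = 3; 45.6 and 25.4 without replicate 3) and at 8.22 and 4.76 in the injured wild type. Knockout CCl4 replicate 3 as the whole source is argued against, since without it the median of these markers was 2.42 log2 and 4 of 23 passed. What remained lay mostly in replicate 2, so its resting on that library is not excluded. On the TMM scale summed macrophage markers were 176 CPM in replicate 1 and 422 in replicate 2. In wild type CCl4 libraries they were 55.0 to 155. The purity of the sort was not measured here. Summed endothelial (1154 CPM) and stellate (378 CPM) markers were also highest of all libraries in knockout CCl4 replicate 3. A rise of macrophages in the injured knockout liver stays open and untested. Of the 23 markers, 5 reached a mean of 1 CPM in wild type untreated libraries and 0 are on another list.

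Pseudogenes and their parent genes stood among the largest genotype differences without injury, with 18.5% of called genes with a position being pseudogenes and 4.65% of tested genes. The summed level of Rps3a1, Rps3a2 and Rps3a3 differed by -0.02 log2 (-0.0225) between untreated genotypes, with Rps3a1 alone at -6.09, which is consistent with reads moving between a parent gene and its copies when the allele differs from the reference. Strain segments carried with the targeted alleles cannot be told apart from none: called genes lay on chromosomes 3 and 9 in 16.4% of cases against 10.2% of tested genes, a ratio of 1.60 (1.603; Fisher exact p = 0.0339, BH-adjusted 0.0339 over 3 tests), between the values of 2 and 1.2 set in advance, with 14 of 651 called on chromosome 3 (2.38 times the rate over all chromosomes), 6 of 731 on chromosome 9 (0.91 times) and 1.77 to 1.97 times on chromosomes 1, 2, 14 and 17. Strain segments elsewhere may add to this, since 25.7% of called genes (25.69) had another within 1 Mb against a median of 15.6% in random sets (permutation p = 0.031, BH-adjusted 0.0339). An effect of Yap and Taz loss on these genes stays open, as untested.

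The median CCl4 effect on 30 cell-cycle genes was larger in knockout by 4.20 log2 with 8 members past the threshold (27 adjusted over the list alone; adjusted p = 9.51e-20, and adjusted p = 0.198 with an estimated correlation), by 4.41 without knockout CCl4 replicate 3 and by 2.71 without wild type untreated replicate 5. Part of this came from untreated samples. The list's median for knockout against wild type was -2.06 log2 untreated (-0.9998 without wild type untreated replicate 5) and 1.77 after CCl4. RNA of the same non-hepatocyte cells is argued against, since knockout CCl4 replicate 1 held 0.881 (0.8808) of the cell-cycle CPM of replicate 3 with 176 against 5883 CPM of macrophage markers. For the part seen after CCl4, a larger share of cycling hepatocytes in the injured knockout is a candidate explanation. Without replicate 3 the list's median over wild type was 2.07 log2 (2.0691), and replicates 1 and 2 lay above all 5 wild type CCl4 libraries. Cycling cells of types other than macrophages were not tested apart. Wild type untreated replicate 5, at 441 CPM, shows that a library can stand high without injury.

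Of 100 splits of the wild type samples, 1 (the real one, with 117 genes) called as many genes after CCl4, and the highest other called 3. In knockout 1 of 35 splits, the real one with 2610, called as many, and the highest other called 578. Without injury 1 of 100 splits by genotype, the real one with 128, called as many, and the highest other called 11. After CCl4 1 of 56 splits, the real one with 1622, called as many, and the highest other called 290. In these 4 comparisons the real split called the most genes of those tried. With 35 to 100 splits this argues against chance as the source of the counts and does not exclude it. Mixed splits also keep the real effect as spread within groups, which lowers their counts. For the difference of CCl4 effects 2 of 100 splits, the real one among them, called at least 150 genes, and the highest other called 548, several times the real count, which points to a structure of the samples. That split exchanges 4 wild type and 4 knockout untreated samples, so by construction it adds the genotype effects with and without injury instead of subtracting them. Splits of this kind do not tell whether chance gives the 150.

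A single library lay far from the others of its group in 5 of 87 checks, where chance gives about 1 in 20. Each check took 1 measure or gene in 1 group. Knockout CCl4, with 3 libraries, was too small a group to be checked. Wwtr1 had 18.8 CPM in wild type untreated replicate 4 against 9.85 to 12.1 in the others, and Mki67 had 31.3 in wild type untreated replicate 5 against 0 to 4.79. Gpnmb had 0.295 in wild type untreated replicate 4 against 0 to 0.0833. That gap rests on few counts, since 3 counts are 0.226 CPM of total counts in that library. Ugt2b38 had 25 in wild type CCl4 replicate 5 against 11.5 to 14.6, and Cyp17a1 had 12.3 in wild type untreated replicate 1 against 4.04 to 5.96.

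The CCl4 effect differed between genotypes by the test of the difference in 10 named genes, with edgeR BH-adjusted p from 0.0204 to 0.0316. The log2 differences were -4.08 for Adh6-ps1, 4.48 for Gsta1, -1.74 for Cyp2c23, 5.04 for Ucp2, -1.49 for Kcnn2, 3.40 for Tagln2, -4.81 for Xlr3a, -3.14 for Gm2788, -2.24 for Nat8f1 and 5.30 for Tnfaip8. Each lost its call when one of at least 5 libraries was left out in turn, with adjusted p up to 0.0576 for Adh6-ps1, 0.0598 for Gsta1 and 0.0814 for Tnfaip8. Without the library that gave that highest p, their log2 differences were -4.03, 4.50 and 5.25, and the calls ended near the threshold. Those libraries were not the ones picked for moving the fold most, so stable folds are not shown. In knockout CCl4 libraries Tnfaip8 had 7.05 ± 8.28 and Ucp2 91.0 ± 95.6 CPM, against 76.5 ± 14.6 for Cyp2c23 (n = 3). For Gsta1, knockout against wild type after CCl4 went from 1.92 to 1.13 log2 without knockout CCl4 replicate 2.

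The CCl4 effect also differed between genotypes for 19 lists by camera with the preset correlation, and for none with an estimated one (lowest adjusted p = 0.198). Median log2 differences were 6.49 for macrophage markers (6.31 with genes at 0 set to their bound), 4.20 for cell cycle, 2.97 for stellate and myofibroblast markers, 2.76 for mitochondrially encoded genes, 2.21 for inflammatory genes, 2.02 for profibrotic genes (1.90 with bounds) and 1.41 for endothelial markers. They were 0.90 for female-biased genes, 0.83 for interferon response, 0.62 for NRF2 response, 0.60 for p53 targets, 0.49 for acute phase and 0.30 for cytosolic ribosomal proteins. They were -1.66 for male-biased genes, -0.68 for periportal genes, -0.58 for bile acid genes, -0.56 for fatty acid oxidation, -0.50 for fatty acid synthesis and -0.39 for hepatocyte identity. With knockout CCl4 replicate 3 left out, 13 of these medians turned sign or moved over 1.5 times. They became 3.11 for macrophage, 1.32 for stellate and -0.18 for endothelial markers, 1.08 for mitochondrially encoded, 0.91 for inflammatory and 1.16 for profibrotic genes. They became 0.40 for female-biased, 0.43 for interferon, 0.40 for p53, 0.06 for acute phase, -0.14 for ribosomal, -0.15 for fatty acid synthesis and -0.34 for fatty acid oxidation genes. The preset-correlation calls were lost there for endothelial (adjusted p = 0.874), ribosomal (0.285), fatty acid synthesis (0.274) and acute phase (0.124) lists, and for p53 targets without knockout CCl4 replicate 2 (0.147). Other single libraries moved medians over 1.5 times as well: cell cycle to 2.71 without wild type untreated replicate 5, p53 to 0.13 without replicate 2 and female-biased to 0.23 without replicate 1 of that group. Male-biased went to -2.83 without knockout CCl4 replicate 1, fatty acid synthesis to -0.81 and ribosomal to 0.53 without knockout CCl4 replicate 2, and hepatocyte identity to -0.24 without knockout untreated replicate 2. Acute phase went to 0.78 and endothelial to 2.12 without wild type CCl4 replicates 1 and 4.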

How the results depend on the processing

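Leaving out the 2 libraries with over 30% mitochondrial counts, and leaving out mitochondrially encoded genes, were chosen after the data were seen. Where a value moved, the cause was not tested unless fewer samples entered the fit. RLE and upper-quartile scaling and leaving out mitochondrial genes kept each of the 5 gene counts within 1.5 times. The 117 genes of CCl4 in wild type became 650 with library totals alone, 494 with DESeq2, 442 with voom quality weights, 49 with the replicate block and 187 without the 2 high-mitochondrial libraries. The 2610 of CCl4 in knockout became 1273 with the 2 compared groups only. The 128 of knockout untreated became 328 with DESeq2 and 213 with quality weights. The 1622 of knockout after CCl4 became 1033 with quality weights, 867 with the block and 555 without the high-mitochondrial libraries. The 150 of the difference of effects became 28 with library totals, 33 without a filter, 88 with the stricter filter, 779 with DESeq2, 9 with voom, 2 with quality weights, 3 with the block, 39 with the surrogate variable and 9 without the high-mitochondrial libraries. Leaving out 1 sample at a time gave 63 to 179, 1666 to 3077, 89 to 152, 418 to 2216 and 0 to 867 genes in the order of the contrasts. The lists called, 17, 18, 12, 18 and 19, became 3, 2, 0, 0 and 0 with an estimated correlation, and 13 to 20, 16 to 21, 7 to 12, 12 to 21 and 16 to 21 with 1 sample left out. Mean Yap1 ranged over 45.6 to 54.7, 52.8 to 58.3, 1.99 to 4.26 and 1.07 to 1.79 CPM, and Wwtr1 over 11.2 to 13.5, 18.7 to 20.7, 1.65 to 2.09 and 3.6 to 5.78, in the order of the groups. Correlations of effects ranged over 0.458 to 0.574 and 0.115 to 0.251. Directions reversed in 10 list results. Ribosomal proteins reversed after CCl4 in wild type with the surrogate variable (adjusted p = 0.15). In CCl4 in knockout, knockout after CCl4 and the difference they reversed without knockout CCl4 replicate 3 (0.0153, 0.0452 and 0.285) and without the high-mitochondrial libraries (0.0187, 0.0456 and 0.263). With 1 sample left out these ranged over 0.0153 to 0.779, 0.00143 to 0.475 and, for the list cytosolic ribosomal proteins in the difference of the CCl4 effect between genotypes, 8.987e-05 to 0.285. Mitochondrially encoded genes, knockout after CCl4, reversed with quality weights (0.992), without that replicate (0.561) and without the high-mitochondrial libraries (0.501), and ranged over 0.000336 to 0.561 with 1 sample left out. Of other list results 3968 kept direction and side of the threshold, 96 gained and 233 lost a call. Of named-gene results 7873 kept both, 4 gained and 1203 lost a call, and 0 reversed. With 11266420 to 24775863 counts per sample, genes near 3 counts per group have folds known only as bounds.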

Other observations

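The comparison of samples with the same replicate number was chosen only after the counts were seen. Of 26 acute phase genes 8 rose and 1 fell after CCl4 in knockout (9 and 1 adjusted over the list alone; camera adjusted p = 0.00624, and adjusted p = 0.522 with an estimated correlation). Lcn2, an iron-trapping lipocalin, rose by 7.06 ± 1.00 log2 and Apcs, a pentraxin, by 2.20 ± 0.42. Without knockout CCl4 replicate 3 5 members rose, the list's median was 0.14 log2 against 0.53 with an adjusted p of 0.051, and the rise of Apcs was 1.40. Of 23 immediate-early genes 7 rose (7 adjusted over the list alone; adjusted p = 5.77e-05, and adjusted p = 0.231 with an estimated correlation), with the zinc finger factor Klf6 up by 4.28 ± 0.49. The list's median was 1.26 log2, and 0.46 without replicate 3 of the injured knockout. In knockout against wild type after CCl4, 5 of its genes were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.00457, and adjusted p = 0.465 with an estimated correlation), and 2 were higher without that library (adjusted p = 0.11).

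For CCl4 against untreated in knockout, Cd36, a fatty acid carrier also made by macrophages, rose by 5.05 ± 0.85 log2. Cyp4a10 and Cyp4a14, which hydroxylate fatty acids, rose there by 2.56 ± 0.60 and 4.09 ± 0.83. Dgat2, which completes triglyceride synthesis, fell by 1.07 ± 0.23, and Tm7sf2, a sterol reductase, fell by 1.17 ± 0.21. Of 25 cholesterol synthesis genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; 3 fell without knockout CCl4 replicate 2), and of 19 circadian clock genes 2 fell (2 adjusted over the list alone), Nr1d2 and Cry2. Without Yap/Taz knockout CCl4 replicate 2 the values of Nr1d2 and Cry2 were -1.21 (adjusted p = 0.0501) and -0.995 (adjusted p = 0.122), against -1.44 and -1.14. The rise of Cd36 was 3.53 without knockout CCl4 replicate 3. Cdkn1a, an inhibitor of cyclin-dependent kinases, was higher in knockout than in wild type after CCl4 by 2.20 ± 0.64 (adjusted p = 0.0358). Its call ended without any 1 of 6 libraries, with 2.22 log2 and an adjusted p of 0.12 without knockout CCl4 replicate 3.

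Lymphocyte and neutrophil markers were too few to test as lists. Lymphocyte markers summed to 4.21, 11.2 and 59.6 CPM in the 3 knockout CCl4 libraries, against 2.67 ± 1.5 in wild type CCl4 (n = 5, up to 5.07). Neutrophil markers summed to 1.97, 3.99 and 31.4 against 1.39 ± 0.483 (up to 1.99). Cholangiocyte markers summed to 106 ± 41.6 (n = 3) against 77.7 ± 11, and erythroid and platelet markers to 58.9 ± 20.7 against 92.0 ± 22.9. Gm42418, which overlaps ribosomal RNA, held 5.39% of counts in wild type untreated replicate 4. Samples with the same replicate number had a mean correlation of -0.0242 after group means were removed, against 0.00637 for different numbers.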
